A study of Mus musculus with 8 samples.

How the data were processed

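DNA of 8 liver tumors from male FAH-/- mice, labelled with Cy5, was hybridized against a common pool of liver DNA from 6 male FAH+/+ littermates, labelled with Cy3, on mouse comparative genomic hybridization arrays. Per the labels 1.5 µg of DNA was digested and labelled per hybridization. The dyes were not swapped, so a bias of the dyes at a probe does not cancel between arrays. Per the labels the mice drank water with 7.5 mg/L NTBC before the dose was reduced.

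The authors extracted the images with Agilent Feature Extraction 10.7.3.1, and the deposited processed signals are intensity values after background subtraction, detrending and linear dye normalization within each array. The deposited log ratios are the log10 of the red tumor signal over the green reference signal, not centred on the median. The deposited table of the series holds the same log10 ratios in rounded form, which differed from those of the arrays by at most 0.00499, with column medians from -0.0171 to -0.00484. The deposited median spot and background signals are intensity values without further processing. Per the file headers the quality marks of the spots are 0 or 1, a unit of the kind other, and probe positions are on mm9 (NCBI37).

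Log2 ratios of red over green processed signals were computed for the 174305 spots that are not controls, spots with an outlier mark on an array were left out on that array (115 to 221 per array), spots of the same probe were averaged, and each array was centred on its median. Between 97.0% and 99.9% of the spots were well above background in both channels. The noise, from differences between neighbouring probes, was 0.62 to 0.65 on the log2 scale in tumors 1 to 6 and 0.39 in tumors 7 and 8.

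Each array was divided into segments by recursive circular binary segmentation, written for this work in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, numba 0.67.0 and scipy 1.17.1. The split threshold was set on simulated noise to 1% false splits per chromosome, probe values were limited to 4 noise SD while splitting, and neighbouring segments were merged below a z of 4. A segment was a gain or a loss at a mean log2 ratio of at least 0.2 in size with at least 5 probes. A chromosome was gained or lost as a whole where at least 80% of its probed length was called in that direction. Plots were drawn with matplotlib 3.10.9.

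After the values had been seen, a second scale was added. The arrays shared a pattern of log2 ratios from probe to probe, with correlations of 0.840 to 0.913 between tumors 1 to 6 and 0.669 to 0.795 for pairs with tumor 7 or 8, groups defined here from the data. The numbers in the sample titles, whose meaning is not given, set the same 2 tumors apart from the other 6. The pattern was skewed, so that array means lay 0.04 to 0.11 above array medians, and the commonest segment level lay 0.02 to 0.25 above the array median (median 0.14). For the second scale, the median over arrays of each probe's log2 ratio, taken after subtracting each array's own chromosome medians, was scaled to each array and subtracted, and the commonest segment level of each tumor was then set to 0. Whole-chromosome changes are kept by this step, and short changes common to most tumors are removed with the pattern. The noise was then 0.12 to 0.21, and correlations between arrays were -0.22 to 0.30. The planned values on array medians stay as the first scale throughout, and the second scale is given beside them.

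Recurrence of whole-chromosome changes was tested by permuting chromosome labels within each tumor (100000 permutations, one-sided, maximum over chromosomes). Recurrence in 1 Mb bins was tested with circular shifts of each tumor's called profile along the autosomes and X (10000 shifts, one-sided). Such shifts had been planned for the gene lists too, but as list genes could be placed by chromosome only, chromosome labels were permuted within each tumor instead (10000 permutations). Every list was tested one-sided for gains and one-sided for losses. The plan had been one-sided for gains of oncogenes and for losses of tumor suppressors, and two-sided for the other lists. Chromosome means were tested against 0 with a two-sided exact sign-flip permutation test and Benjamini-Hochberg adjustment over 19 autosomes and X. Shifts of 1 Mb bin means across the tumors were tested in R 4.3.3 with limma 3.58.1 (intercept only, treat with a log2 size of 0.1, adjusted p under 0.05). The slides were compared by an exact permutation test over 70 splits.

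Before the data were examined, the tests, the lists and a rule for what is named were fixed. The rule takes up to 8 members per list whose chromosome was called in at least 2 tumors, the 10 most recurrent regions per direction and up to 10 segments under 3 Mb per direction with a log2 ratio of at least 0.8 in size. Of what it takes, the text gives the regions and genes that recur most or hold on both scales, and this choice, like the naming of Tert, Tsc2, Pik3r1, Trp53, Nfe2l2, the 2 limma bins and any longer segment, was made after the values were seen. The planned tests of genes and of Fah could not be run, because the files name no genes and no gene positions on mm9 were given. 1 Mb bins took the place of genes, list genes were placed by chromosome, and 11 lists of gene families that need positions were not run.

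Simulated data had independent, symmetric noise around 0 with the median noise SD of these arrays. All 12 of 12 whole chromosomes at a log2 ratio of 0.3 were recovered, as were all 48 of 48 segments of 10 Mb at 0.3. All 46 of 46 segments of 1 Mb at 0.8 were recovered too, and 0.106% of unchanged probes were called. In limma, on independent simulated bins with the SD of the real ones, 94 of 100 bins shifted by 0.4 were recovered. Of those shifted by 0.8, 100 of 100 were recovered, with 1 false call among 2549 bins. Neither simulation held the shared probe pattern, its skew or the offset of the centring, so these rates of false calls do not cover errors from them.

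The alternatives tried were normexp background subtraction with an offset of 50, the deposited table, centring on the peak of the density, other filters of spots, call thresholds of 0.1 and 0.3, at least 3 or 10 probes per segment, a hidden Markov model in place of the segmentation, 0.1% false splits, whole chromosomes at 60% or 95% of the length, regions shared by 7 tumors left out, other limma settings, and each tumor left out in turn. Alternatives chosen after seeing the data were the second scale, the same with a threshold of 0.1, with the pattern from the other arrays, or without tumors 7 and 8, segment medians in place of means, the commonest level set to 0 with the pattern kept, and gene lists with 1 permutation of chromosome labels for all tumors.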

Results

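Genomic DNA of liver tumors from 8 individual male FAH-/- mice was compared with a pool of liver DNA from 6 male FAH+/+ littermates by array comparative genomic hybridization, in which tumor and reference DNA carry different dyes and compete for the same probes. Fah encodes fumarylacetoacetate hydrolase, the last enzyme of tyrosine breakdown. Mice that lack it live on NTBC (nitisinone), a drug that blocks the pathway at an earlier step. Here the mice had been kept on 2.5% of their usual dose over a period of between 6 and 12 months. The labels form 1 group of 8 tumors, which are called tumors 1 to 8 in the order of deposition and are the replicates throughout. Each array held 174305 probe spots for 170305 different probes, 170183 of them on the autosomes and X, at a median spacing of 10.9 kb. The median spot signal was 4.24 to 11.3 times the local background in the reference channel and 4.19 to 6.56 times in the tumor channel. The number of arrays limits the precision. The reference is a single pool, so the spread between control mice is not part of any error given, and no normal liver of a tumor mouse was on an array. On this scale, for a chromosome with 2 copies, a gain of 1 copy in every cell would give a log2 ratio of 0.58 and the loss of 1 of 2 copies would give -1. These values do not apply to X and Y in these male mice. The number of copies per cell and the share of changed cells were not measured, so the ratios do not give copy numbers.

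The comparison of the 8 tumors with the wild-type pool asks which chromosomes changed in copy number. Chromosome 15 was gained as a whole in tumors 3, 4, 5, 6 and 8, and chromosome 12 was lost as a whole in tumors 1, 4, 6 and 8. These calls held on both scales used here, the first centred on the array median and the second with a probe pattern shared by all arrays subtracted and the commonest segment level of each tumor set to 0. Chromosome 15 carries Myc, a transcription factor that drives cell growth, and Rictor, a core part of an mTOR complex, and chromosome 12 carries Akt1, a growth kinase, and Gstz1, the enzyme of tyrosine breakdown just before Fah. The mean log2 ratio of chromosome 15 was 0.40 ± 0.23 (SD, n = 8) on the first scale, with 0.71 in tumor 5 as the highest and 0.033 in tumor 7 as the lowest. It was 0.25 ± 0.24 (SD, n = 8) on the second scale. The mean of chromosome 12 was -0.13 ± 0.22 (SD, n = 8) on the first scale and -0.27 ± 0.25 (SD, n = 8) on the second, on which tumor 1 had the lowest value of -0.69.

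**Figure D1:**
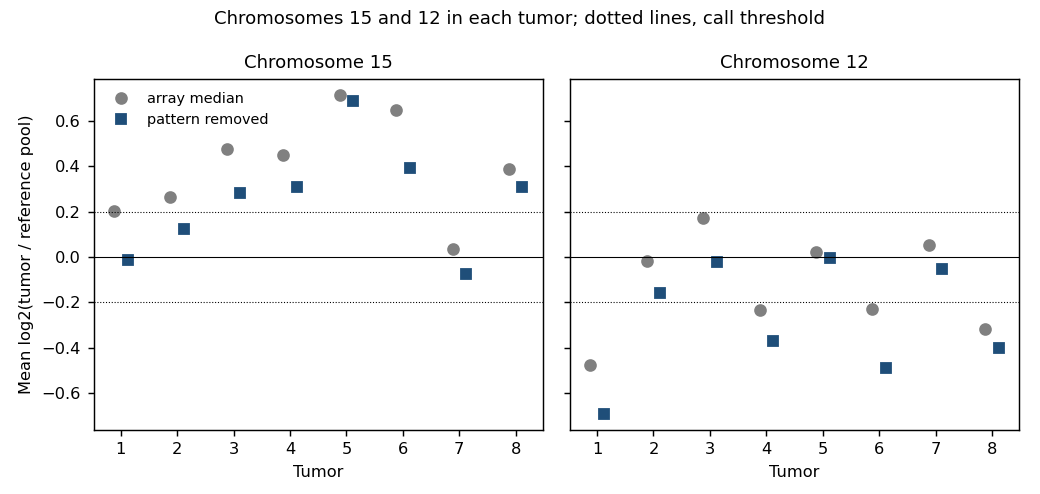
Mean log2 ratio of tumor to reference pool (vertical axes) over chromosome 15 and chromosome 12 in each of the 8 tumors (horizontal axes). Grey circles are centred on the array median, blue squares have the shared probe pattern removed and the commonest segment level at 0, and dotted lines mark the call threshold of 0.2 in either direction. On the blue squares 5 tumors lie above the upper line for chromosome 15 and 4 lie below the lower line for chromosome 12.

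Gains of chromosome 15 recurred more often than tumors with the same number of gains would share by chance. On the first scale 6 tumors gained it (one-sided permutation p = 0.0052, largest count over 20 chromosomes), tumor 2 with a mean of 0.26 being the additional one. On the second scale 5 tumors gained it (permutation p = 5.0e-05). For chromosome 12 losses, 4 tumors gave a permutation p of 0.00198 on the first scale and 0.028 on the second. Each count rests on few tumors: without tumor 2 or without tumor 8 the permutation p of chromosome 15 on the first scale was 0.0677 and 0.0675, and without tumor 1, 4, 6 or 8 that of chromosome 12 on the second scale was 0.162, 0.318, 0.089 and 0.32. Centring on the peak of each array's density ended both calls (permutation p = 0.614 for chromosome 15 and 0.15 for chromosome 12), as did a call threshold of 0.1 for chromosome 15 (permutation p = 0.0793) and of 0.3 for chromosome 12 (permutation p = 1.0). Chromosome 12 also missed the threshold on the second scale at a call threshold of 0.1 (permutation p = 0.0505) or without tumors 7 and 8 (permutation p = 0.32), and with the commonest level at 0 and the pattern kept (permutation p = 0.0699). Leaving out each tumor in turn left the chromosome 15 permutation p on the second scale at 0.00055 or below.

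Further whole chromosomes changed in single tumors, and 8 gains and 10 losses among 160 chromosome-by-tumor pairs were called on both scales. Tumor 5 gained chromosomes 14, 15, 16 and 17, with means of 0.42, 0.71, 0.74 and 0.39 on the first scale and 0.39, 0.69, 0.72 and 0.37 on the second. Tumor 1 lost chromosomes 4, 12 and 13, with means of -0.47, -0.48 and -0.45 on the first scale and -0.67, -0.69 and -0.66 on the second. Tumor 6 lost chromosomes 8, 12, 13, 14 and X, with means of -0.24, -0.23, -0.22, -0.23 and -0.26 on the first scale and -0.49, -0.49, -0.47, -0.49 and -0.50 on the second. Chromosome 13, which carries Tert, the catalytic part of telomerase, was thus lost in 2 tumors (permutation p = 0.869 on the first scale). The other chromosome counts depend on where the value 0 is set. On array medians there were 36 whole gains and 10 losses, 5 of the losses remaining without tumor 6. With the pattern removed and the commonest level at 0 there were 8 gains and 16 losses. Of these, 4 gains remained without tumor 5 and 10 losses without tumor 6. The 6 added losses were chromosomes 1, 3, 6, 7 and 18 in tumor 3 and chromosome 9 in tumor 6. Their means in tumor 3 were -0.30, -0.31, -0.28, -0.29 and -0.26, and chromosome 9 in tumor 6 had a mean of -0.46 (-0.21 on array medians). Of the 28 gains called only on array medians, 21 lie in tumors 1 and 6, whose commonest segment level was 0.22 and 0.25 above the array median. No pair was called in opposite directions. Normexp background subtraction gave 9 gains and 10 losses and called 8 of the 8 gains and 9 of the 10 losses shared by both scales.

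**Figure D2:**
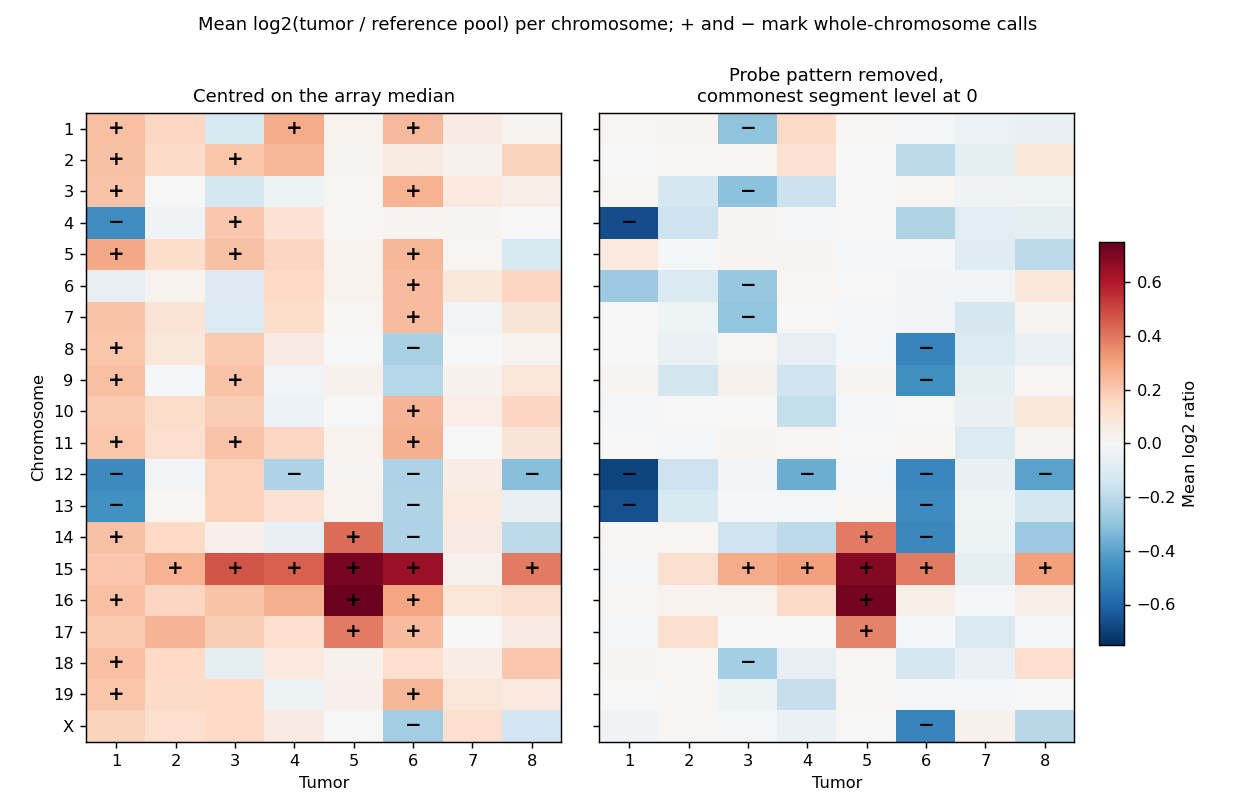
Mean log2 ratio of tumor to reference pool by chromosome (vertical axis) and tumor (horizontal axis), in red above 0 and blue below 0, with + and − marking whole-chromosome gains and losses. The left panel is centred on the array median, with 36 gains and 10 losses. The right panel has the shared probe pattern removed and the commonest segment level at 0, with 8 gains and 16 losses.

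The mean log2 ratio of each chromosome was also tested against 0 over the 8 tumors. On array medians chromosomes 2, 11, 15 and 16 were above 0 in 8 of 8 tumors, with means of 0.14, 0.14, 0.40 and 0.26. For each of them the two-sided exact sign-flip p was 0.00781, the smallest that 8 tumors can give, and the Benjamini-Hochberg adjusted p over 20 chromosomes was 0.0391. A chromosome alone at this smallest p does not pass the adjustment, so each pass rests on several chromosomes sharing it. With the pattern kept and only the centring changed to the commonest level, the means of chromosomes 2 and 11 were -0.00095 and -0.0023, and on the second scale they were -0.0052 and -0.0066, so their distance from 0 depends on the centring. The chromosome 16 mean was 0.12 ± 0.24 (SD, n = 8) on the second scale (above 0 in 7 of 8 tumors, exact p = 0.0234, adjusted p = 0.117), and without tumor 5 it was 0.040 there and 0.20 on array medians. On the second scale 0 chromosomes passed. Chromosome 15 was above 0 in 6 of 8 tumors, with an exact sign-flip p of 0.0313 and an adjusted p of 0.125. Chromosome 12 was below 0 in 8 of 8, with an exact sign-flip p of 0.00781 and an adjusted p of 0.117. At that smallest p it could not have passed on its own. Among the 8, tumors 3, 5 and 7 lay close to 0, at -0.023, -0.0067 and -0.054. Every autosome of tumor 7 was below 0 on this scale. The signs of these values depend on where 0 is set. On array medians chromosome 12 was below 0 in 5 of 8 tumors, with an exact p of 0.133 and an adjusted p of 0.221. Fah lies on chromosome 7, whose mean was 0.084 ± 0.12 (SD, n = 8) on array medians with an exact p of 0.0938 and an adjusted p of 0.17. On the second scale the mean was -0.058 ± 0.11 (SD, n = 8), below 0 in 6 of 8 tumors, with an exact p of 0.0938 and an adjusted p of 0.234. Tumor 6 gained this chromosome as a whole on array medians, with a mean of 0.24, and tumor 3 lost it on the second scale, with a mean of -0.29. The probes inside Fah could not be placed, because the files name no genes and no gene positions on mm9, the mouse genome build of the probe positions, were at hand. No chromosome passed with any tumor left out, where the smallest exact p is 0.0156 and still more chromosomes would have to share it.

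The share of the genome in called gains and losses describes how far each tumor departed from the wild-type pool. Tumor 6 was altered over 40.3% of the probed length and tumor 3 over 34.2% with the pattern removed, and most of this was loss, with 36.4% and 30.4% of the length. Tumor 5 was the exception, with 15.8% of its length gained and 0.518% lost. Tumor 2 had the smallest share, 2.20%. The median over the 8 tumors was 17.2% ± 12.5 (SD, n = 8), with medians of 3.91% gained and 11.7% lost. On array medians gains made up most of the share, with medians of 17.6% gained and 4.30% lost, and tumor 3 had 38.5% gained and 0.0% lost and tumor 6 54.0% gained and 25.9% lost, and with only the centring changed to the commonest level the medians were 3.8% gained and 13.7% lost, so the balance of gain and loss depends on the centring. On that scale the median share was 21.6% ± 29.8 (SD, n = 8), and tumors 1 and 6 reached 80.9% and 79.9%, against 18.5% and 40.3% on the second scale. After the order of the probes was shuffled, at most 0.118% of the length was called on array medians and at most 0.635% with the pattern removed. For the latter the shuffled values were centred on the array mean, not on the commonest level. Shuffling removes differences between regions, so these rates do not cover errors from the centring. The 0.118% was that of tumor 1, whose called share was 80.9% on array medians and 18.5% on the second scale.

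**Figure D3:**
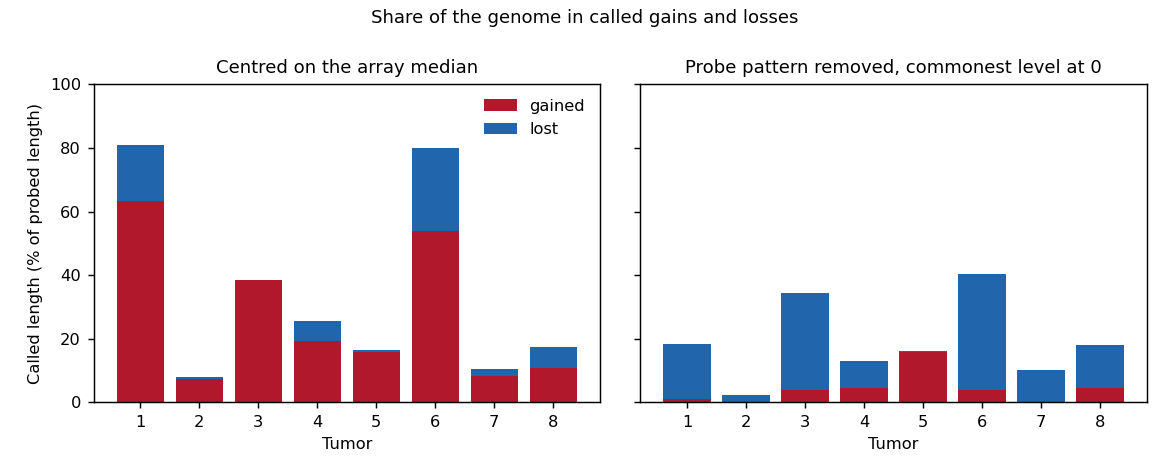
Share of the probed length in called gains (red) and losses (blue), in percent (vertical axes), for each of the 8 tumors (horizontal axes). The bars are stacked and start at 0. On array medians (left) tumors 1 and 6 reach 80.9% and 79.9%, and with the shared probe pattern removed and the commonest segment level at 0 (right) the highest share is 40.3% in tumor 6.

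Within chromosomes, the recurrent gains lay along all of chromosome 15. With the pattern removed, all 101 bins of 1 Mb on chromosome 15, of 2549 bins in the genome, were gained in at least 4 tumors and passed a circular-shift permutation test corrected for the maximum over bins. The region 15:46000001-47000000 was gained in 6 tumors, with a permutation p of 0.0001, the smallest that 10000 shifts can give. The regions 15:5000001-46000000 and 15:47000001-73000000 were gained in 5 tumors each (permutation p = 0.0017). On array medians 11 bins passed, all in 15:14000001-25000000, which was called gained in 8 of 8 tumors (permutation p = 0.0015). Its means ran from 0.19 in tumor 1, below the commonest segment level of that tumor (0.215), to 0.72 in tumor 5. With the pattern removed its means were -0.056 in tumor 1, 0.18 in tumor 2 and 0.084 in tumor 7, under the call threshold of 0.2. In the other tumors they ran from 0.226 in tumor 3 to 0.664 in tumor 5. Bins of recurrent loss passed the test near the distal end of chromosome 12. The region 12:113000001-115000000 was lost in 6 tumors on both scales, with a permutation p of 0.0001, the smallest the shifts can give, on array medians and 0.0392 with the pattern removed. These were the 4 tumors that lost the whole chromosome and tumors 2 and 7. With the pattern removed tumors 2 and 7 were at -0.24 and -0.26, against chromosome 12 means of -0.16 and -0.054. Relative to the chromosome mean, the region was at 0.040, -0.0086, 0.042 and -0.075 in tumors 1, 4, 6 and 8. Tumors 1 and 6 were thus not deeper there than over the whole chromosome. The region 12:106000001-109000000 was lost in 6 tumors with the pattern removed (permutation p = 0.0392), with means of -0.62 in tumor 1 and 0.05 in tumor 3. Tumors 2 and 7 were again among the 6, at -0.25 and -0.31 against chromosome 12 means of -0.16 and -0.054. Tumor 7 had the highest noise on this scale, 0.21, and the most called segments, 291. On array medians the mean of this region lay below -0.2 only in tumors 1 and 8, at -0.31 and -0.34. On array medians the count of recurrent gain bins was 19 without tumor 1 and 40 without tumor 7, and that of loss bins, 2 with all tumors, was 4 without tumor 1 or tumor 6. Gain bins were 0 under density-peak centring or a call threshold of 0.1, and also with regions shared by 7 tumors left out, which removes them by construction. Loss bins were 0 under the hidden Markov model, and on the second scale at a threshold of 0.1 or without tumors 7 and 8.

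**Figure D4:**
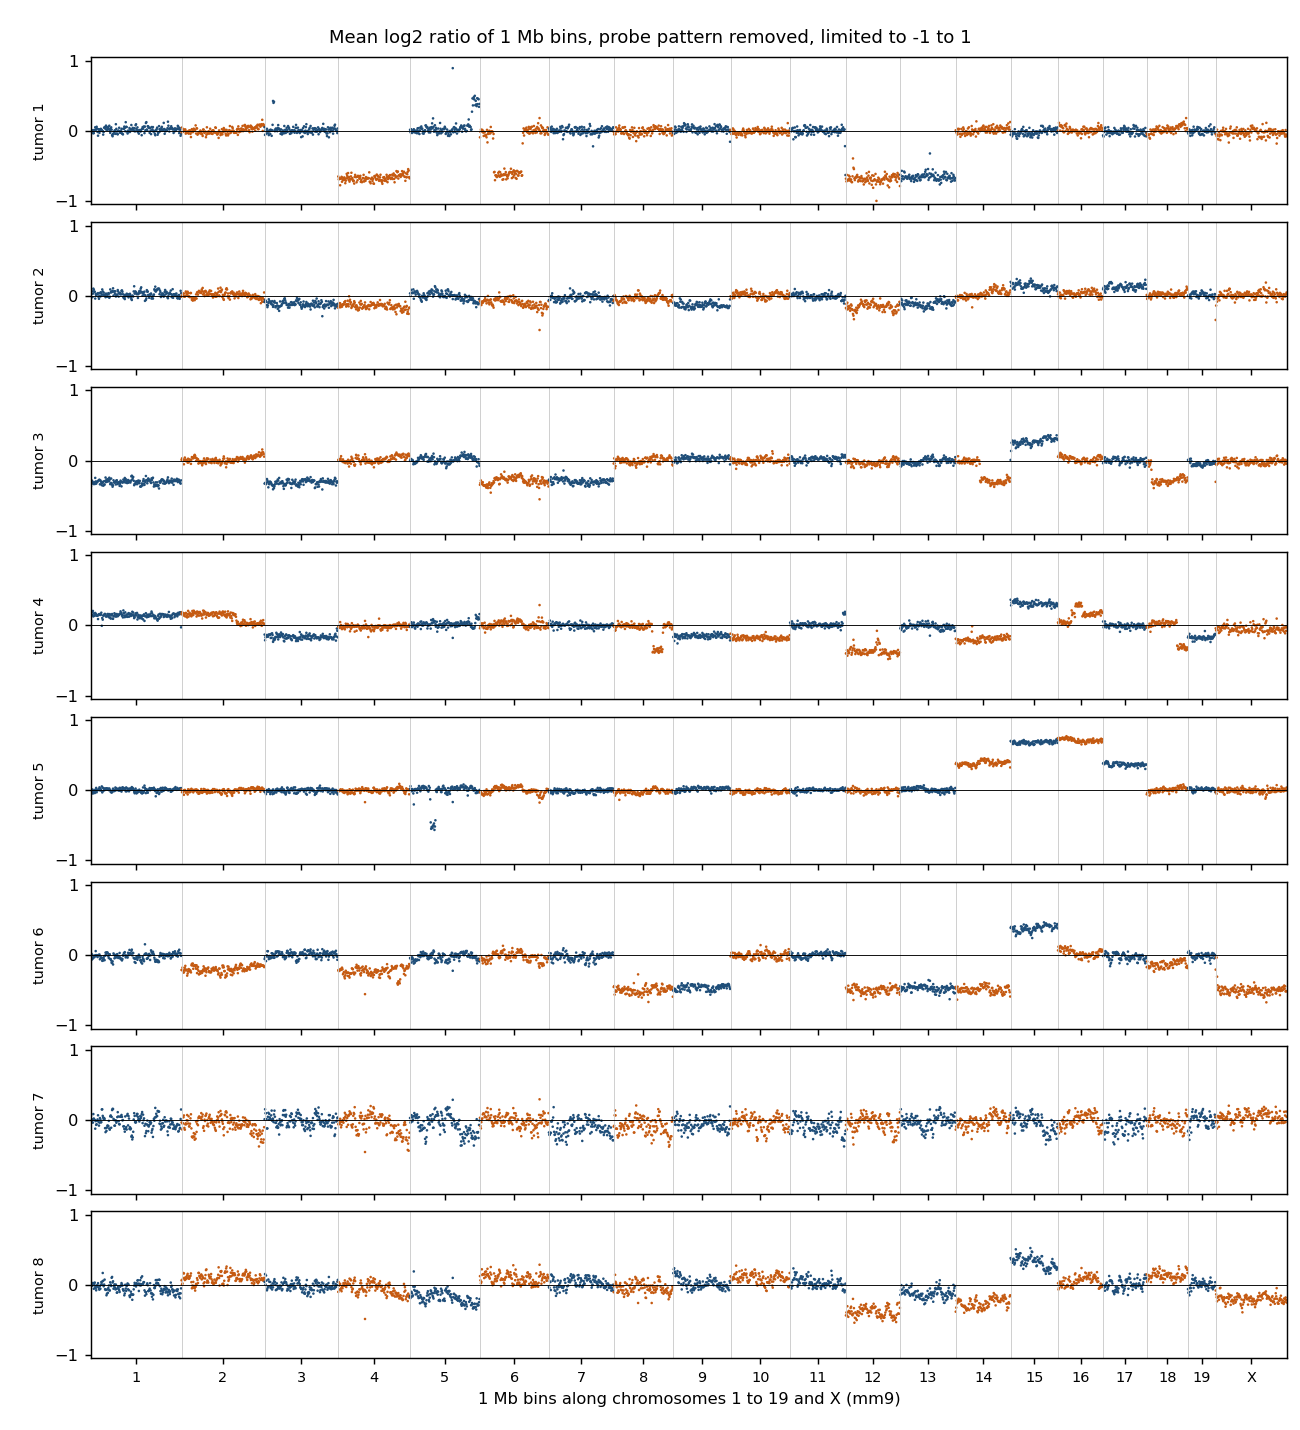
Mean log2 ratio of tumor to reference pool in 1 Mb bins (vertical axes, limited to -1 to 1) along chromosomes 1 to 19 and X (horizontal axis) for the 8 tumors, with the shared probe pattern removed and the commonest segment level at 0. Each dot is a bin, colors alternate between chromosomes, and the bins of chromosome 15 lie above 0 in tumors 3, 4, 5, 6 and 8.

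Short segments were described by a rule fixed beforehand, those under 3 Mb with a log2 ratio of at least 0.8 in size. The deepest loss was 12:70976008-71327433 in tumor 1, 351 kb with 35 probes, at -1.64 ± 0.15 (SE over probes). It lay within the lost chromosome 12 of that tumor and reached -1.96 with the pattern removed, against a chromosome mean of -0.69. In tumor 6 the region 14:11145164-11307782, 163 kb with 16 probes, was at -1.23 ± 0.13 (SE over probes), within its lost chromosome 14. Another region, 13:108579209-108702580 in tumor 6, 123 kb with 12 probes, stood at -1.17 ± 0.043 (SE over probes) with the pattern removed. The highest short gain was 16:46059975-46115156, 55.2 kb with 5 probes, called in 7 tumors and highest in tumor 5 with 2.86 ± 0.60 (SE over probes). Its values with the pattern removed were -0.12 to 0.85, since a change common to most arrays is subtracted with the pattern by construction. Counted once for each tumor, 57 short gains and 4 short losses were called on array medians, and 4 gains and 23 losses with the pattern removed. All 57 gains overlapped a called gain of another tumor, and 13 of them overlapped called gains in 7 or more tumors. With the pattern removed the 4 gains also overlapped one of another tumor, and 6 of the 23 losses overlapped none. These regions were not matched to genes, for want of gene positions on mm9.

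Shifts common to the tumors were tested in limma on 1 Mb bins, which took the place of genes. Chromosome 15 held 93 of the 257 bins that were higher than the pool, chromosome 16 held 42 and chromosome 17 held 25, and chromosome 12 held 7 of the 10 bins that were lower (treat against a log2 size of 0.1, adjusted p under 0.05, n = 8). In this test bin 15 45, at 15:45000001-46000000 with 33 probes, had a mean log2 ratio of 0.73 ± 0.20 (SD, n = 8) and a limma adjusted p of 1.5e-08. On chromosome 12, bin 12 113, at 12:113000001-114000000 with 74 probes, had a mean of -0.34 ± 0.22 (SD, n = 8) and a limma adjusted p of 0.00519. With only the centring changed to the commonest level, limma called 6 bins higher and 8 lower, so the count of higher bins depends on the centring. With the pattern removed as well it called 0 bins in either direction, and 79 bins were higher and 113 lower at an unadjusted p under 0.05.

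Genes of 8 lists fixed beforehand were counted as gained or lost where their whole chromosome was called. All 185 entries were placed on a chromosome through the RefSeq table, which is on the GRCm38 assembly and served for chromosome names only. On chromosome 15, gained in 6 tumors on array medians and 5 with the pattern removed, lie the oncogenes Myc and Rictor, the tumor suppressors Arid2 and Kmt2d, which act on chromatin, and Stk3, a kinase of the Hippo pathway, the DNA repair gene Xrcc6, and Rad21 and Espl1, which hold and release sister chromatids. On chromosome 12, lost in 4 tumors, lie Akt1, Gstz1 and Sav1, another member of the Hippo pathway. Neighbouring genes of a chromosome share these counts and are not independent.

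The mTOR pathway list, 19 genes of the growth control around the mTOR kinase, had 43 gene-by-tumor gains on array medians against 34.2 expected. This did not pass (permutation of chromosome labels within each tumor, one-sided, adjusted p = 0.309 over 14 tests). A two-sided test had been planned for this list. With the pattern removed it had 17 gains against 7.58 expected (permutation, adjusted p = 0.0042), and with normexp background subtraction it had 17 against 8.54 (permutation, adjusted p = 0.028). On array medians it passed without tumor 1, with 36 gains against 23.8 expected (permutation, adjusted p = 0.007). These p values are not separate from the recurrence of chromosome 15, since labels permuted in each tumor on its own remove it and 15 of the 17 gains with the pattern removed lie on that chromosome. With 1 permutation of the labels for all tumors, which keeps the recurrence, the list did not pass (permutation p = 0.0396, adjusted p = 0.554 with the pattern removed, adjusted p = 0.741 with normexp, 0.212 without tumor 1 and 0.613 on array medians). With the pattern removed, its members gained in at least 2 tumors were Rictor, Deptor and Prkaa1, 3 genes that share chromosome 15. Deptor inhibits the mTOR kinase and Prkaa1 encodes a subunit of AMPK, which restrains mTOR, so members with opposite roles were gained together. Mlst8, Tsc2 and the list's other members were gained in at most 1 tumor each on that scale, and 2 members were lost in at least 2 tumors, Akt1 in 4 and Pik3r1 on chromosome 13, a regulatory subunit of PI3 kinase, in 2. On array medians 11 of the 19 members were gained in at least 2 tumors, against 3 with only the centring changed.

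The other 6 lists tested did not pass in either direction on either scale. Their counts of gained members depend on the centring. On array medians 32 of 48 liver tumor suppressors, 21 of 40 liver tumor oncogenes, 14 of 23 p53 and DNA damage genes, 17 of 22 NRF2 genes, 11 of 22 mitotic checkpoint genes and 4 of 10 genes of tyrosine breakdown were gained in at least 2 tumors, and with only the centring changed to the commonest level these counts were 3, 2, 1, 1, 2 and 0. Counts of lost members also moved with the pattern, and 11 liver tumor suppressors and 6 oncogenes were lost in at least 2 tumors with the pattern kept and the commonest level at 0. The counts that follow are those with the pattern removed. Of the 48 liver tumor suppressors, 3 were gained and 1 was lost in at least 2 tumors with the pattern removed, with 28 gene-by-tumor gains against 19.3 expected (permutation, adjusted p = 0.372) and 27 losses against 38.4 expected (adjusted p = 0.976). Of the 40 liver tumor oncogenes, 2 were gained and 3 lost in at least 2 tumors, with 11 gains against 16 expected and 31 losses against 32 expected (permutation, adjusted p = 0.976 for each). Of the 10 genes of tyrosine breakdown, Gstz1 was lost in 4 tumors and none was gained in more than 1 (7 losses against 7.94 expected, permutation, adjusted p = 0.976). Hpd, the enzyme that NTBC blocks, and Qdpr on chromosome 5 were gained in 3 tumors on array medians and in 0 with the pattern removed. Of the 23 p53 and DNA damage genes, Xrcc6 was gained in 5 tumors and Trp53 on chromosome 11 in 0 (3 on array medians), with 6 gains against 9.18 expected (permutation, adjusted p = 0.976). Of the 22 NRF2 oxidative stress genes, Maff was gained in 5 tumors and Nfe2l2 on chromosome 2 in 0 (2 on array medians), with 6 gains against 8.82 expected (permutation, adjusted p = 0.976). Of the 22 genes of the mitotic checkpoint and chromosome segregation, Rad21 and Espl1 were gained in 5 tumors, with 10 gains against 8.79 expected (permutation, adjusted p = 0.976).

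The arrays came from 2 slides of 4 arrays each, tumors 1 to 4 on the first and tumors 5 to 8 on the second. Chromosome 15 was gained in 2 tumors of the first slide and 3 of the second with the pattern removed, with means of 0.17 ± 0.15 and 0.33 ± 0.31 (SD, n = 4, exact permutation p = 0.429 over 70 splits). Chromosome 12 was lost in 2 tumors of each slide, with means of -0.31 ± 0.29 and -0.24 ± 0.24 (SD, n = 4, exact permutation p = 0.743). The altered share of the second slide minus that of the first was -7.16 percentage points on array medians, 31.1% against 38.3%, and 4.27 points with the pattern removed, 21.3% against 17.0% (two-sided exact permutation p = 0.657 on each scale).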

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

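The tests of the shared probe pattern and of chromosome 15 were chosen after their results had been seen, and the bounds for the region on chromosome 16 were written before, although the allowance for its spread was added after the ratio was known. The design gives 1 group, so no biological explanation from the design was tested, and the only biological difference weighed was one in copy number between the mice themselves and the pool, for the probe pattern and the region on chromosome 16.

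The log2 ratios of all 8 arrays shared a pattern from probe to probe that made up 65.2% to 95.3% of the variance of each array. Copy-number differences between the tumor mice and the pool would be shared by neighbouring probes, and the correlation of the pattern between neighbouring probes was 0.0102, which argues against them as the main source. The slide is argued against as well, because tumors 5 and 6 followed the pattern with slopes of 1.06 and 1.07 while tumors 7 and 8 on the same slide had slopes of 0.58 and 0.608. Between these pairs the tumor channel differed along the pattern with a slope of -0.469 and the reference channel with a slope of -0.00045. A probe-dependent signal of the tumor DNA channel is thus a candidate source of this difference in amplitude. The reference channel held the same pool on every array, so this comparison cannot place the part of the pattern common to all arrays. The origin of the pattern, such as the dye, the labelling or the state of the DNA, was not tested and stays open. So does a batch, since the unexplained numbers in the sample titles also set tumors 7 and 8 apart from the rest.

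Chromosome 15 gains in several tumors were weighed against 3 technical explanations. A bias of the probes of chromosome 15 would raise every array, and with the pattern removed the lowest value was -0.074, in tumor 7. Every autosome of tumor 7 was below 0 on that scale, from -0.13 on chromosome 7 to -0.014 on chromosome 19. The sign of its chromosome 15 alone therefore says little about such a bias. Its value lay within the range of its other autosomes, and chromosome 15 of tumor 1 was at -0.014. The skewed probe pattern together with median centring would leave no recurrence once both are corrected, and the permutation p was then 5.0e-05 with 5 tumors. The slide would place the gains on 1 slide, which 5 tumors cannot show where a slide holds 4 arrays, so this count decides nothing about the slide. The smaller number of gains per slide was 2. A gain of chromosome 15 in the DNA of these tumors remains as a hypothesis, found and tested on the same data.

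The region 16:46059975-46115156 was called as a short gain in 7 tumors, on 5 probes. For probe bias scaled as the shared pattern, the bound was a ratio of tumors 7 and 8 to tumors 1 to 6 of at most 0.75. For more copies in the tumor mice than in the pool it was at least 0.85. The first bound is loose, since slopes on the pattern were 0.58 and 0.608 in tumors 7 and 8 and 1.03 to 1.08 in tumors 1 to 6. Strict scaling would give a ratio well under it. With each tumor's chromosome 16 median subtracted, since tumor 5 gained that chromosome, the ratio was 0.735, with 0.749 in tumor 7 and 0.72 in tumor 8, and the values of tumors 1 to 6 had a relative spread of 0.0505 (SD over mean). On array medians the ratio was 0.692 and the relative spread 0.136. On both the ratio lies below the first bound by less than that spread, so probe bias and a copy-number difference of the mice cannot be told apart on 1 region of 5 probes. Without the allowance for spread, which was added after the ratio was known, both ratios meet the bound for probe bias. They do not reach the bound for more copies.

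Among 53 groups of 8 values tested for a value far from the others, 15 held one, and chance gives about 1 in 20. Values of the same chromosome on both scales are not independent. Tumor 5 stood apart with 15.8% of its length gained on the second scale, and with a chromosome 16 mean of 0.74 on the first scale and 0.72 on the second. Tumor 1 stood apart on chromosome 4, with means of -0.47 and -0.67. Tumor 3 stood apart on the second scale on chromosome 1, with -0.30, and on chromosome 7, with -0.29. Tumor 6 stood apart on chromosome 8, with -0.24 on the first scale and -0.49 on the second, and on the second scale on chromosome 9, with -0.46, and on chromosome X, with -0.50. Chromosome Y of tumor 6, on 122 probes, stood at -0.42 on the first scale and -0.65 on the second. On the second scale tumor 7 had the lowest value of the 8 tumors on chromosome 11, with -0.10, and tumor 4 that on chromosome 19, with -0.17. Every autosome of tumor 7 was below 0 on that scale.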

How the results depend on the processing

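The second scale and the other alternatives named last below were chosen after seeing the data, and the rest were fixed beforehand. On the first scale there were 36 whole gains and 10 losses, a median altered share of 21.6%, permutation p values of 0.0052 for chromosome 15 and 0.00198 for chromosome 12, 4 chromosomes past the test of means, 11 recurrent gain bins and 2 loss bins, 0 gene lists past the test and 257 limma bins up and 10 down. The deposited table and the absence of a filter on marked spots kept each of these on its side of the threshold, counts within 1.5-fold and the share within 1 SD between tumors (29.8). So did at least 3 or 10 probes per segment for the values that rest on called segments, and 60% or 95% of the length for whole gains and losses, both p values and the lists. Of the values under settings fixed beforehand 215 stayed within these limits, 46 moved further, 43 lost a call, 1 gained one and 2 reversed, and of the added ones 42 stayed within them, 41 moved further, 16 lost a call and 16 reversed. The cause of a change was not tested unless given. The signal was at 4.19 times the background or more, and whether this limits shallow changes was not tested. The correction for GC content, the test of genes and that of Fah were not run.

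Normexp background subtraction gave 9 gains, 0 chromosomes past the test, 102 gain bins, 1 list, 137 limma bins up and 19 down, and turned the slide difference from -7.16 to 4.35 points (p = 0.571, exact permutation). Centring on the density peak, which moves 0 down by 0.07 to 0.33, gave 100 gains and 4 losses, a share of 77.7%, permutation p values of 0.614 for chromosome 15 and 0.15 for chromosome 12, 17 chromosomes, 0 gain bins, 1870 limma bins up and 2 down, and turned the chromosome 12 mean to 0.080. A call threshold of 0.1 gave 72 gains and 17 losses, a share of 65.5%, p = 0.0793 (permutation) for chromosome 15, 0 gain bins and 13 loss bins. A threshold of 0.3 gave a share of 6.76%, over 3-fold lower but within that SD, 7 gains, 3 losses, p = 1.0 (permutation) for chromosome 12, 81 gain bins and 1 list. Gain bins numbered 19 with probes well above background on all arrays, 103 under the hidden Markov model, with 0 loss bins, and 88 at 0.1% false splits. Leaving out regions shared by 7 tumors takes out parts of chromosome 15, so by construction its permutation p was 1.0 and gain bins were 0. In limma, eBayes gave 851 bins up and 80 down, treat with 0.2 gave 66 and 2, and slide as a random block gave 352 and 18.

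Leaving out each tumor in turn gave 25 to 36 gains, 5 to 10 losses (5 without tumor 6), permutation p values of 0.00013 to 0.0677 for chromosome 15 and 0.00198 to 0.0372 for chromosome 12, 0 to 0 chromosomes past the test (the smallest exact p of 7 tumors is 0.0156), 11 to 40 gain bins (40 without tumor 7, 19 without tumor 1), 2 to 4 loss bins (4 without tumor 1 or 6), 0 to 1 lists (1 without tumor 1), 185 to 279 limma bins up and 7 to 15 down. On the second scale there were 4 to 8 gains (4 without tumor 5) and 10 to 16 losses (10 without tumor 6). The ranges of the permutation p there were 5.0e-05 to 0.00055 for chromosome 15 and 0.00239 to 0.32 for chromosome 12.

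The second scale gave 8 gains, 16 losses, 0 chromosomes, 101 gain bins, 5 loss bins, 1 list, 0 limma bins in either direction and a slide difference of 4.27. With the pattern from the other arrays it gave 8, 16, 0, 101, 6, 1, 0 and 4.90 for the same values. With a threshold of 0.1 it gave a share of 34.0%, 11 gains, 28 losses, p = 0.0505 (permutation) for chromosome 12, 84 gain bins, 0 loss bins, 1 list and a slide difference of 3.36. Without tumors 7 and 8 it gave 7 gains, p = 0.32 (permutation) for chromosome 12, 0 chromosomes, 99 gain bins, 0 loss bins, 1 list and 0 limma bins in either direction. Segment medians gave 8 gains, 16 losses, 103 gain bins, 8 loss bins, 1 list and a slide difference of 3.38. The commonest level at 0 with the pattern kept gave 8 gains, 19 losses, p = 0.0699 (permutation) for chromosome 12, 0 chromosomes, 85 gain bins, 9 loss bins, 1 list, 6 limma bins up and a slide difference of 4.08. The list was the mTOR pathway in each case, with adjusted p from 0.0042 to 0.028. With 1 permutation of chromosome labels for all tumors, which keeps the recurrence of chromosome 15, 0 lists passed on either scale (adjusted p = 0.554 for the mTOR pathway on the second). The means of chromosomes 2, 7 and 11 turned to -0.0052, -0.058 and -0.0066 on the second scale, to -0.0053, -0.058 and -0.0068 with the pattern from the other arrays and to -0.00095, -0.055 and -0.0023 with the pattern kept, and those of chromosomes 2 and 7 to -0.0096 and -0.060 without tumors 7 and 8, where chromosome 11 was at 0.0050.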

Other observations

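The stretches of chromosome and the lower call threshold given here were chosen after their values had been seen. Parts of chromosomes were changed as well as whole ones, as stretches of at least 10 Mb in which called segments of the same direction were joined over gaps of up to 2 Mb on the second scale. Tumor 1 had lost 60.9 Mb of chromosome 6 (6:33230044-94158984) at a mean of -0.63 and had gained 16.1 Mb at the distal end of chromosome 5 (5:136387909-152519030) at 0.43. Tumor 3 had lost 64.4 Mb of chromosome 14 (14:60785903-125164256) at -0.29. Of the same chromosome tumor 4 had lost 51.6 Mb at -0.22, and tumor 8 had lost 44.1 Mb and 25.3 Mb at -0.29 and -0.32. Tumor 6 had lost chromosome 14 as a whole. Tumor 4 had lost 22.5 Mb of chromosome 8 (8:87594415-110087005) at -0.35 and 22.6 Mb at the distal end of chromosome 18 (18:68140662-90730147) at -0.32. Tumor 5 had lost 11.4 Mb of chromosome 5 (5:46497585-57882170) at -0.52, in a tumor whose whole-chromosome changes were gains. Losses were also called on array medians on chromosome 6 in tumor 1, at -0.46, and on chromosomes 8 and 18 in tumor 4, at -0.25 and -0.23. The loss on chromosome 5 in tumor 5 was called there too, at -0.55. In tumor 8, 11.4 Mb and 27.9 Mb of chromosome 14 were called lost on array medians, at -0.26 each. No stretch of chromosome 14 was called lost on array medians in tumor 3 or tumor 4.

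Tumor 2 had few calls at a threshold of 0.2, with 2.20% of its length on the second scale, and 33.0% at a threshold of 0.1. At that lower threshold its chromosome 15 was gained as a whole with a mean of 0.12, and its chromosomes 4, 9 and 12 were lost with means of -0.15, -0.14 and -0.16. The shares at that threshold were 48.6% in tumor 4, 32.5% in tumor 7 and 49.9% in tumor 8, against 13.1%, 10.2% and 18.2% at 0.2. Tumor 5 changed least, from 16.3% to 16.5%.

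Of the 8 tumors, 3 had both the gain of chromosome 15 and the loss of chromosome 12 on the second scale, 2 had the gain alone, 1 had the loss alone and 2 had neither (two-sided Fisher exact p = 1.0).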
